A study of Homo sapiens with 6 samples.

How the data were processed

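RNA was measured in cultured human uterine leiomyoma cells, which come from a benign tumour of uterine smooth muscle. Per the labels' protocols, the cells were kept for 24 h in phenol red-free medium with stripped serum and either 50 µg/ml genistein, an isoflavone of soy, or the vehicle, 0.3% dimethyl sulfoxide. RNA from flasks of the same treatment was pooled, amplified and labelled with Cy3 or Cy5. Each of 6 two-colour Agilent whole human genome arrays paired 1 of 3 genistein RNAs with the same pooled vehicle RNA, and each genistein RNA was hybridised once in Cy3 and once in Cy5.

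The deposited scanner files hold the mean intensity of each spot and the median intensity of its local background in both channels, as written by Agilent Feature Extraction, version 7.5 per the labels. They also hold a log10 ratio of Cy5 over Cy3, which per the file headers was made by that software after background subtraction and dye normalization, and a p-value of that ratio on 1 array, which the authors took into a further program to combine arrays, per the labels. The deposited value table of the series holds the log10 ratio with its sign turned to genistein over vehicle, and differed from the scanner files by at most 4.99e-06. The medians of its 6 columns were 0, -0.00406, 0, 0, 0.00126 and 0, so no further centring was seen and its scale and direction were known.

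Mean intensities were corrected for background with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and spots with an outlier flag in either channel were left out, and spots of 1 probe were averaged. Of 41000 probes, 19499 were named through an accession in the reference gene table of assembly GRCh38.p14, 268 through a symbol, 210 through an older symbol and 96 through a symbol in the probe description. The other 20927 carry an accession or clone name only, and count among the probes but not among the genes. The 61 probes of XIST and Y-linked genes were left out. A probe was kept when it was well above background in the genistein channel or in the vehicle channel on at least 3 of the 6 arrays, which left 38503 probes and 15063 genes. Each gene was represented by its brightest kept probe. Another probe of the gene was called in the opposite direction for 7 of the called genes, among them ORC6 and FGFR1.

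Every log2 ratio was turned to genistein over vehicle by the dyes in the labels, and the 2 arrays of 1 genistein RNA were averaged, which gave 3 replicates. The mean ratio was tested against 0 with limma's moderated test (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all kept probes and calls at an adjusted p under 0.05. The vehicle pool is 1 control sample, so the control's own spread is not in the test. Nothing in the labels says that the 3 genistein RNAs came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Other splits of the samples could not be drawn, since 3 treated samples stand against 1 pool. The number of arrays limits the precision.

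A set of 32 gene lists was fixed in advance from textbook knowledge, and each was tested against the other genes with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Members counted are those measured, and other members were not analysed here. The lists cover the TGF-beta pathway and its target genes, matrix, contractile, cell cycle, stress, lipid, lysosome, signalling, growth factor, ribosomal and cell type marker genes. No list call held with an estimated correlation, so that p is given with each called list. With 3 replicates that correlation is estimated from 2 residual degrees of freedom. The same adjusted p of 0.538 came out for mitosis genes and for fibroblast markers, at 1.14e-08 and 0.261 with the preset correlation. A call lost in this way therefore cannot tell a list without a shift from a test with little power, and does not secure the call either. The named genes were fixed by a rule, also in advance. They are the 8 largest rises and 8 largest falls among called genes with the same direction on all 6 arrays, the 3 members of each list with the lowest adjusted p, and 14 genes of the TGF-beta pathway, the cell cycle and the steroid receptors that were named whatever their result. Chosen after their values were seen were TP53I3, GDF15, COL1A1 and COL3A1, and those members that moved one way in a list in groups of 5 or fewer.

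These lists, this rule and the other settings tried were chosen before the data were examined, with 1 exception given here. The settings changed the background correction, the source of the ratios, the normalization, the filter, the spread model and the use of the dye swaps. They also added a slide series term and changed the threshold, the probes per gene, the set test and the replicates used. Fits on the arrays of 1 dye orientation count the dye effect as treatment. Fits without 1 doubted array, that of replicate 1 with genistein in Cy5, were added after the data were seen. Replicate 1 was then its other array alone, so the dyes were not balanced. A second such fit took the 5 arrays singly, with a dye term and a random block by replicate, and its values are given as such. The block correlation was -0.047 there and -0.026 in a like fit of all 6 arrays. Both fits therefore count the 2 arrays of 1 genistein RNA as nearly separate samples. Their p-values do not measure the spread between genistein RNAs alone. Slides came from 2 number series of 3 arrays each. The scan days were not used here. The fit was tested on simulated data for this comparison: of 38503 simulated probes with the measured spread, the fit recovered 95.5% of 67 probes changed 1.5-fold and 100% of 67 changed 2-fold, with 13 false calls beside 197 true ones. With 0.5 of the change in replicate 1, it recovered 46.3% and 85.1%.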

Results

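Genome-wide RNA levels were compared between uterine leiomyoma cells given 50 µg/ml genistein for 24 h and cells given the vehicle, in 3 genistein RNAs against 1 pooled vehicle RNA. Each genistein RNA was measured on 2 arrays with the dyes exchanged. Median spot intensities were 350.8 to 433 in Cy3 and 397.1 to 427.7 in Cy5, over median local backgrounds of 277 to 289. Between 86.7% and 93.8% of probes were well above background in the genistein channel of an array, and between 90.2% and 94.7% in the vehicle channel. Values are log2 ratios of genistein over vehicle, with the SD of the 3 replicates.

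The first comparison asked which genes differ after genistein. Genes of smooth muscle contraction, matrix and mitosis were among the falls, and genes of lipid synthesis among the rises. Of 15063 genes, 697 were higher and 2220 lower, and 168 of the higher and 543 of the lower changed at least 1.5-fold. Over all kept probes, 1576 were higher and 4210 lower. Among genes with the same direction on all 6 arrays, the largest rises were those of AVPI1 (log2 ratio 2.25 ± 0.65, SD, n = 3, limma adjusted p = 0.0237), DEPP1 (2.07 ± 0.70) and HMOX1 (1.95 ± 0.54), which encodes the heme-degrading heme oxygenase 1. Within that group they were followed by the lipogenic transcription factor gene SREBF1 (1.67 ± 0.51), the cholesterol exporter ABCA1 (1.66 ± 0.62), the glutamate receptor subunit GRIN2C (1.56 ± 0.50), the histone gene H2AC18 (1.51 ± 0.48) and SAT1 (1.45 ± 0.49), an enzyme of polyamine breakdown. The proteoglycan gene ESM1 fell by 2.16 ± 0.64 on the log2 scale (limma adjusted p = 0.0237), the smooth muscle actin gene ACTG2 by 1.96 ± 0.52, the retinaldehyde reductase gene DHRS3 by 1.94 ± 0.54 and the prostacyclin synthase gene PTGIS by 1.9 ± 0.49. The transcription factor gene EGR1 fell by 1.82 ± 0.63, the smooth muscle actin gene ACTA2 by 1.79 ± 0.64, the semaphorin and VEGF co-receptor gene NRP1 by 1.75 ± 0.43 and LYPD1 by 1.62 ± 0.40. The p53 target genes TP53I3 (2.38 ± 0.91, adjusted p = 0.0238) and GDF15 (2.36 ± 0.88, adjusted p = 0.0238) rose further, and were picked out after their values were seen because they were lower, not higher, on the array of replicate 1 with genistein in Cy5 (-0.14 and -0.34). The array of replicate 1 with genistein in Cy5 stood apart from the other 5, and without it 1543 genes were higher and 2927 lower, among them 2840 of the 2917 called with it, in the same direction. Without it, 282 of the higher and 830 of the lower genes changed at least 1.5-fold. The means and SDs of the largest rises and falls above include that array, on which each of them lay nearest 0. Without it, the log2 ratio was 2.595 for AVPI1 and -2.41 for ESM1. No gene was called without replicate 2 or without replicate 3 (limma, 4051 and 3482 genes at an unadjusted p under 0.05), against 3353 without replicate 1. None was called with no background subtraction (5206 at an unadjusted p under 0.05), where the lowest adjusted p was 0.054.

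**Figure D1:**
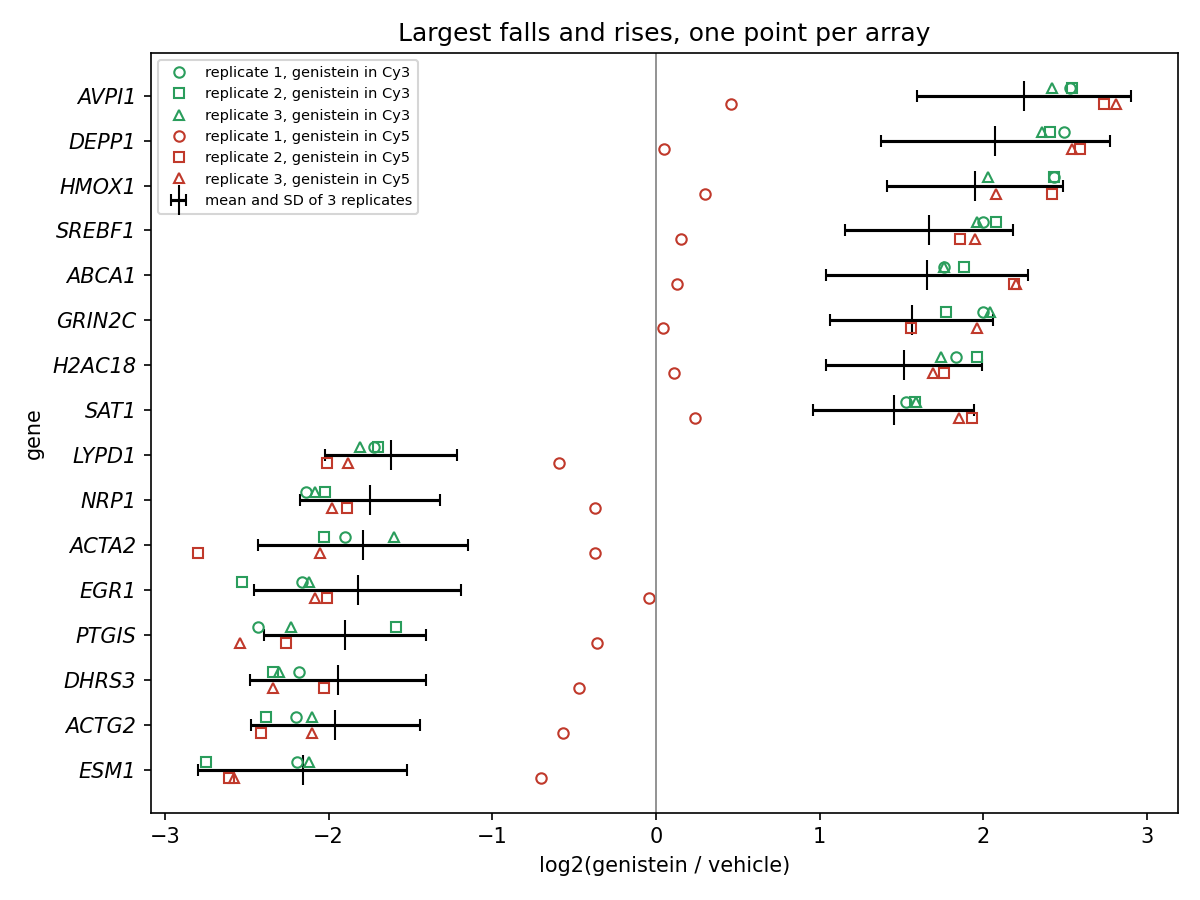
Log2 ratios of genistein over vehicle for the 16 genes named as largest rises and falls among those with the same direction on all 6 arrays, with each array as a point (shape for replicate, colour for the dye of genistein) and the mean and SD of the 3 replicates as a bar. The array of replicate 1 with genistein in Cy5 lies nearest 0 in each gene, for example at 0.46 for AVPI1, where the other arrays lie between 2.42 and 2.81.

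The study's title names a fall of TGF-beta pathway genes, so both TGF-beta lists are not independent evidence of their direction. Of 83 measured pathway members, 5 were higher and 18 lower (8 and 24 adjusted over the list alone). The activin subunit gene INHBA fell by 0.55 ± 0.28 (SD, n = 3, adjusted p = 0.0395), the ligand gene TGFB2 by 0.38 ± 0.09 (adjusted p = 0.0237) and the receptor gene TGFBR2 by 0.22 ± 0.03 (adjusted p = 0.0294, and without the array that stood apart 0.0691, or 0.0161 with a dye term). The sorting nexin gene SNX6 fell by 0.67 ± 0.17 and the transcription factor gene E2F4 by 0.59 ± 0.17. The higher members were the ligand gene TGFB1 (0.71 ± 0.35, adjusted p = 0.0356), the transcriptional regulators ID1 (0.70 ± 0.12), ID3 (0.48 ± 0.10) and TGIF1 (0.35 ± 0.10), and the co-receptor gene TGFBR3 (0.33 ± 0.12). TGFB1 stood at 1.15 to 1.34 on the arrays with genistein in Cy3 and at -0.39, 0.10 and 0.81 on the others. TGFB3 (-0.04), TGFBR1 (-0.002), SMAD2 (-0.24, adjusted p = 0.0526), SMAD4 (-0.09, adjusted p = 0.208) and SMAD7 (-0.02) did not pass the test. SMAD3 was not among the genes tested. As a set the pathway list missed the threshold (camera adjusted p = 0.114, median -0.03). Of 34 TGF-beta target genes, 1 was higher, JUNB (0.23 ± 0.05), and 13 were lower (7 and 14 adjusted over the list alone), with the list at a camera adjusted p of 0.0767. The actin-binding gene CNN1 fell by 1.52 ± 0.47, and the metalloproteinase genes ADAM19 and ADAM12 by 1.43 ± 0.33 and 0.80 ± 0.20. Without that array, 9 pathway genes were higher and 25 lower, and 4 and 15 target genes. SMAD2 then passed (-0.30, adjusted p = 0.00645). The target list reached an adjusted p of 0.0305 and the pathway list 0.117, and over 12 alternatives with camera they ranged from 0.0305 to 0.611 and from 0.0902 to 0.684.

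Falls outnumbered rises among collagen, matrix and contractile genes. Of 51 measured collagen and matrix genes, 19 were lower and 1, FBN2 (0.68 ± 0.12), was higher (28 and 4 adjusted over the list alone, camera adjusted p = 0.00011). That call was lost with an estimated correlation (adjusted p = 0.538). The collagen crosslinking enzyme gene LOXL1 fell by 1.14 ± 0.30, COL16A1 by 1.03 ± 0.30 and SPARC by 0.83 ± 0.16. The fibrillar collagen genes COL3A1 and COL1A1, picked out after their values were seen, fell by 1.63 ± 0.61 and 1.45 ± 0.54 (limma adjusted p = 0.0238 for both). Of 31 smooth muscle contractile genes, 18 were lower and 1, SYNM (0.66 ± 0.19), was higher (22 and 1 adjusted over the list alone, camera adjusted p = 1.58e-05, and adjusted p = 0.538 with an estimated correlation). Besides ACTG2 and CNN1, the actin and myosin binding gene CALD1 fell by 1.23 ± 0.40. Of 34 matrix proteases and inhibitors, 8 were lower and 2 higher (9 and 12 adjusted over the list alone, camera adjusted p = 0.706). The urokinase gene PLAU fell by 1.41 ± 0.29, the aggrecanase gene ADAMTS5 by 1.29 ± 0.37 and the collagenase gene MMP1 by 1.18 ± 0.03, while MMP14 (0.80 ± 0.26) and CTSL (0.76 ± 0.39) rose. Among 14 fibroblast markers 4 were lower and 0 higher (5 and 0 adjusted over the list alone, limma, 2 higher at an unadjusted p under 0.05, camera adjusted p = 0.261): PDGFRA fell by 1.08 ± 0.31, FAP by 0.50 ± 0.06, LUM by 0.38 ± 0.11 and NT5E by 0.20 ± 0.03. NT5E stood at 0.01 to 0.13 on the arrays with genistein in Cy3 and at -0.47 to -0.50 on the others, and without the doubted array lost its call (adjusted p = 0.201) or, with a dye term, kept it (0.00733). Without that array, 28 matrix genes were lower and 3 higher, 20 contractile genes lower and 1 higher, 8 protease and inhibitor genes lower and 10 higher, and 3 fibroblast markers lower and 0 higher. A dye term in that fit gave 5 higher matrix genes, 2 higher contractile genes, and 6 lower and 1 higher fibroblast markers.

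The called genes of cell division and ribosomes fell, with the exception of ORC6. Of 66 measured G2/M and mitosis genes, 33 were lower and 0 higher (39 and 0 adjusted over the list alone, limma, 0 higher at an unadjusted p under 0.05), with a camera adjusted p of 1.14e-08 and an adjusted p = 0.538 with an estimated correlation. The kinetochore genes NDC80 and SPC25 fell by 1.30 ± 0.45 and 0.83 ± 0.24, the cytokinesis gene ECT2 by 0.51 ± 0.15 and the proliferation marker gene MKI67 by 0.16 ± 0.02 (adjusted p = 0.0494). MKI67 stood at -0.30 to -0.33 on the arrays with genistein in Cy3 and at -0.07 to 0.04 on the others. Of 50 G1/S and DNA replication genes, 17 were lower and 1 higher (25 and 3 adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.538 with an estimated correlation). UHRF1, which maintains DNA methylation, fell by 1.07 ± 0.36, the replicative helicase gene MCM5 by 0.56 ± 0.20 and the clamp loader gene RFC4 by 0.41 ± 0.11. The higher member was the origin recognition gene ORC6 (0.32 ± 0.15), of which another probe was called lower. Of 47 ribosomal protein genes, 18 were lower and 0 higher (32 and 0 adjusted over the list alone, limma, 0 higher at an unadjusted p under 0.05). The camera adjusted p was 8.71e-07, and the adjusted p = 0.566 with an estimated correlation. RPL24 fell by 0.60 ± 0.13, RPL5 by 0.50 ± 0.13 and RPL30 by 0.45 ± 0.09. The ribosomal list lost its call on the 3 arrays with genistein in Cy5, which include the doubted array (adjusted p = 0.334, with a range of 1.08e-12 to 0.566 over 12 alternatives with camera). Without the doubted array, 34 of its members were lower. Without that array, 39 G2/M genes were lower and 0 higher, and 24 G1/S genes lower and 3 higher. The cell cycle inhibitor gene CDKN1A, at 0.10 ± 0.05, did not pass the test (adjusted p = 0.182).

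Stress and damage response genes moved in both directions. Of 46 measured p53 target genes, 12 were higher and 4 lower (16 and 6 adjusted over the list alone, camera adjusted p = 0.00376, and adjusted p = 0.538 with an estimated correlation). TP53INP1, a regulator of autophagy and apoptosis, rose by 1.72 ± 0.59 and PHLDA3 by 0.98 ± 0.29. CDKN1A, also a member of this list, did not pass the test (0.10 ± 0.05, limma adjusted p = 0.182). The lower members were the death receptor gene FAS (-0.66 ± 0.13), BTG1 (-0.33 ± 0.11), the polymerase gene POLK (-0.24 ± 0.06) and TIGAR (-0.21 ± 0.07). Of 33 NRF2 target genes, 14 were higher and 3 lower (15 and 4 adjusted over the list alone, camera adjusted p = 0.00419, and adjusted p = 0.538 with an estimated correlation). Besides HMOX1, the ferritin light chain gene FTL (0.83 ± 0.18) and the sulfiredoxin gene SRXN1 (0.83 ± 0.23) rose, and CBR3 (-0.39 ± 0.11), TALDO1 (-0.30 ± 0.12) and NFE2L2 (-0.29 ± 0.06), the gene of NRF2 itself, fell. Of 32 endoplasmic reticulum chaperone and unfolded protein response genes, 11 were higher and 3 lower (15 and 4 adjusted over the list alone, camera adjusted p = 0.0022, and adjusted p = 0.605 with an estimated correlation). The disulfide isomerase gene P4HB (0.72 ± 0.20) and the lectin chaperone gene CANX (0.51 ± 0.17) rose, and SEC24D (-0.54 ± 0.26), DERL2 (-0.54 ± 0.07) and SEC61B (-0.46 ± 0.14), genes of vesicle coating, membrane extraction and translocation, fell. Of 33 heat shock response genes, 14 were lower and 4 higher (18 and 7 adjusted over the list alone, camera adjusted p = 0.049, and adjusted p = 0.546 with an estimated correlation). The mitochondrial co-chaperonin gene HSPE1 fell by 1.09 ± 0.27, HSPA4 by 1.04 ± 0.33 and the chaperonin subunit gene CCT2 by 0.84 ± 0.21, while CRYAB (0.72 ± 0.11), HSP90AA1 (0.62 ± 0.12), HSPA1A (0.51 ± 0.14) and HSPA1L (0.36 ± 0.10) rose. In the integrated stress response list, 8 of 44 members were higher and 8 lower (13 and 11 adjusted over the list alone, camera adjusted p = 0.224). The transcription factor gene CEBPB rose by 1.34 ± 0.37, and CEBPG and the methionyl-tRNA synthetase gene MARS1 fell by 0.49 ± 0.07 and 0.80 ± 0.17. Median centring in place of loess ended the calls of the p53 list (adjusted p = 0.126, range 0.000291 to 0.538 over 12 alternatives with camera) and the chaperone list (0.0585, range 4.09e-05 to 0.605). The arrays with genistein in Cy5 alone, the doubted one among them, called neither (0.14 and 0.0927), nor the NRF2 list (0.0927, range 0.000162 to 0.538). The heat shock list was called in 6 of the 12, with adjusted p from 0.0227 to 0.546 and 0.0639 without replicate 2. The integrated stress response list was called in 1, the arrays with genistein in Cy3 (0.0189, range 0.0189 to 0.697). Without the doubted array, 19 p53 target genes were higher and 6 lower, 14 and 3 NRF2 target genes, 17 and 3 chaperone genes, 6 and 17 heat shock genes, and 14 and 10 integrated stress response genes. CBR3 then lost its call (adjusted p = 0.0722), but kept it with a dye term (0.000972), which gave 6 lower NRF2 target genes.

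Rises outnumbered falls among genes of lipid synthesis, lysosomes and metal binding. Of 31 measured cholesterol and fatty acid synthesis genes, 15 were higher and 1, FDPS (-0.41 ± 0.17), was lower (17 and 1 adjusted over the list alone, camera adjusted p = 2.96e-05, and adjusted p = 0.538 with an estimated correlation). The desaturase gene SCD rose by 1.77 ± 0.59 and the sterol sensor gene INSIG1 by 1.03 ± 0.28, beside SREBF1. Of 48 lysosome and autophagy genes, 8 were higher and 3 lower (15 and 4 adjusted over the list alone, camera adjusted p = 0.00139, and adjusted p = 0.566 with an estimated correlation). The sialidase gene NEU1 rose by 1.80 ± 0.72 (adjusted p = 0.0249), and ATG16L1 (-0.45 ± 0.04), SGSH (-0.36 ± 0.07) and ATP6V1H (-0.18 ± 0.02) fell. Of 11 metallothionein and zinc transport genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone, limma, 0 lower at an unadjusted p under 0.05), with a camera adjusted p of 0.0022 and an adjusted p = 0.538 with an estimated correlation. The zinc exporter gene SLC30A1 rose by 1.39 ± 0.61 (adjusted p = 0.0279) and MT1M by 0.98 ± 0.48 (adjusted p = 0.035), while MT1E, at 0.56 ± 0.33, did not pass (adjusted p = 0.0527). Median centring ended the calls of the lysosome list (adjusted p = 0.152, range 4.5e-06 to 0.566 over 12 alternatives with camera) and the metallothionein list (0.0585, range 8.05e-05 to 0.538). The lysosome call was also lost on the arrays with genistein in Cy5, the doubted one among them (0.14). Without the doubted array, 16 lipid synthesis genes were higher and 1 lower, 26 and 5 lysosome and autophagy genes, and 7 and 0 metallothionein genes. MT1E was then among the latter (adjusted p = 0.000916).

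Falls outnumbered rises among growth factor, NF-kappa-B and YAP and TAZ target genes, and rises outnumbered falls among immediate-early genes. Over all genes 2220 were lower and 697 higher, and camera called none of those lists with more falls. Of 26 measured ERK feedback genes, 8 were lower and 0 higher (12 and 0 adjusted over the list alone, limma, 0 higher at an unadjusted p under 0.05), with a camera adjusted p of 0.00283 and an adjusted p = 0.538 with an estimated correlation. Beside EGR1, the ERK inhibitor gene SPRY2 fell by 1.20 ± 0.10 and the chromatin protein gene HMGA2 by 1.02 ± 0.34. Of 40 receptor tyrosine kinase and growth factor genes, 12 were lower and 1, FGFR3 (0.34 ± 0.17), was higher (13 and 1 adjusted over the list alone, camera adjusted p = 0.0767). The ligand genes VEGFC and PDGFC fell by 1.43 ± 0.27 and 1.26 ± 0.37, as did the receptor gene PDGFRA. Of 30 immediate-early genes, 9 were higher and 2, EGR1 and CCN1 (-1.02 ± 0.39), were lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.049, and adjusted p = 0.538 with an estimated correlation). JUND rose by 0.71 ± 0.20 and the phosphatase gene DUSP1 by 0.40 ± 0.06. Of 42 NF-kappa-B and inflammatory genes, 12 were lower and 0 higher (14 and 2 adjusted over the list alone, limma, 3 higher at an unadjusted p under 0.05, camera adjusted p = 0.0767). The chemokine genes CCL2, CCL7 and CXCL1 fell by 1.21 ± 0.37, 1.04 ± 0.17 and 0.85 ± 0.16. Of 28 YAP and TAZ target genes, 6 were lower and 2, LATS2 (0.42 ± 0.07) and GADD45B (0.24 ± 0.05), were higher (12 and 3 adjusted over the list alone, camera adjusted p = 0.0645), and FJX1 fell by 0.85 ± 0.26. The ERK feedback call was lost under median centring (adjusted p = 0.0506, range 0.00132 to 0.538 over 12 alternatives with camera) and on the arrays with genistein in Cy3 (0.0688). The immediate-early list was called in 4 of the 12 (range 0.0235 to 0.538), not without replicate 2 (0.0804) or the doubted array (0.0529). The YAP and TAZ list was called without replicate 1 (0.0238) and without the doubted array (0.0108, range 0.0108 to 0.538). The receptor and growth factor list was called without replicate 1 (0.0426, range 0.0426 to 0.538). Without the doubted array, 9 ERK feedback genes were lower and 0 higher, 14 and 2 receptor and growth factor genes, 4 and 11 immediate-early genes, 13 and 2 NF-kappa-B genes, and 12 and 2 YAP and TAZ targets. GADD45B then lost its call (adjusted p = 0.274, or 0.137 with a dye term).

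**Figure D2:**
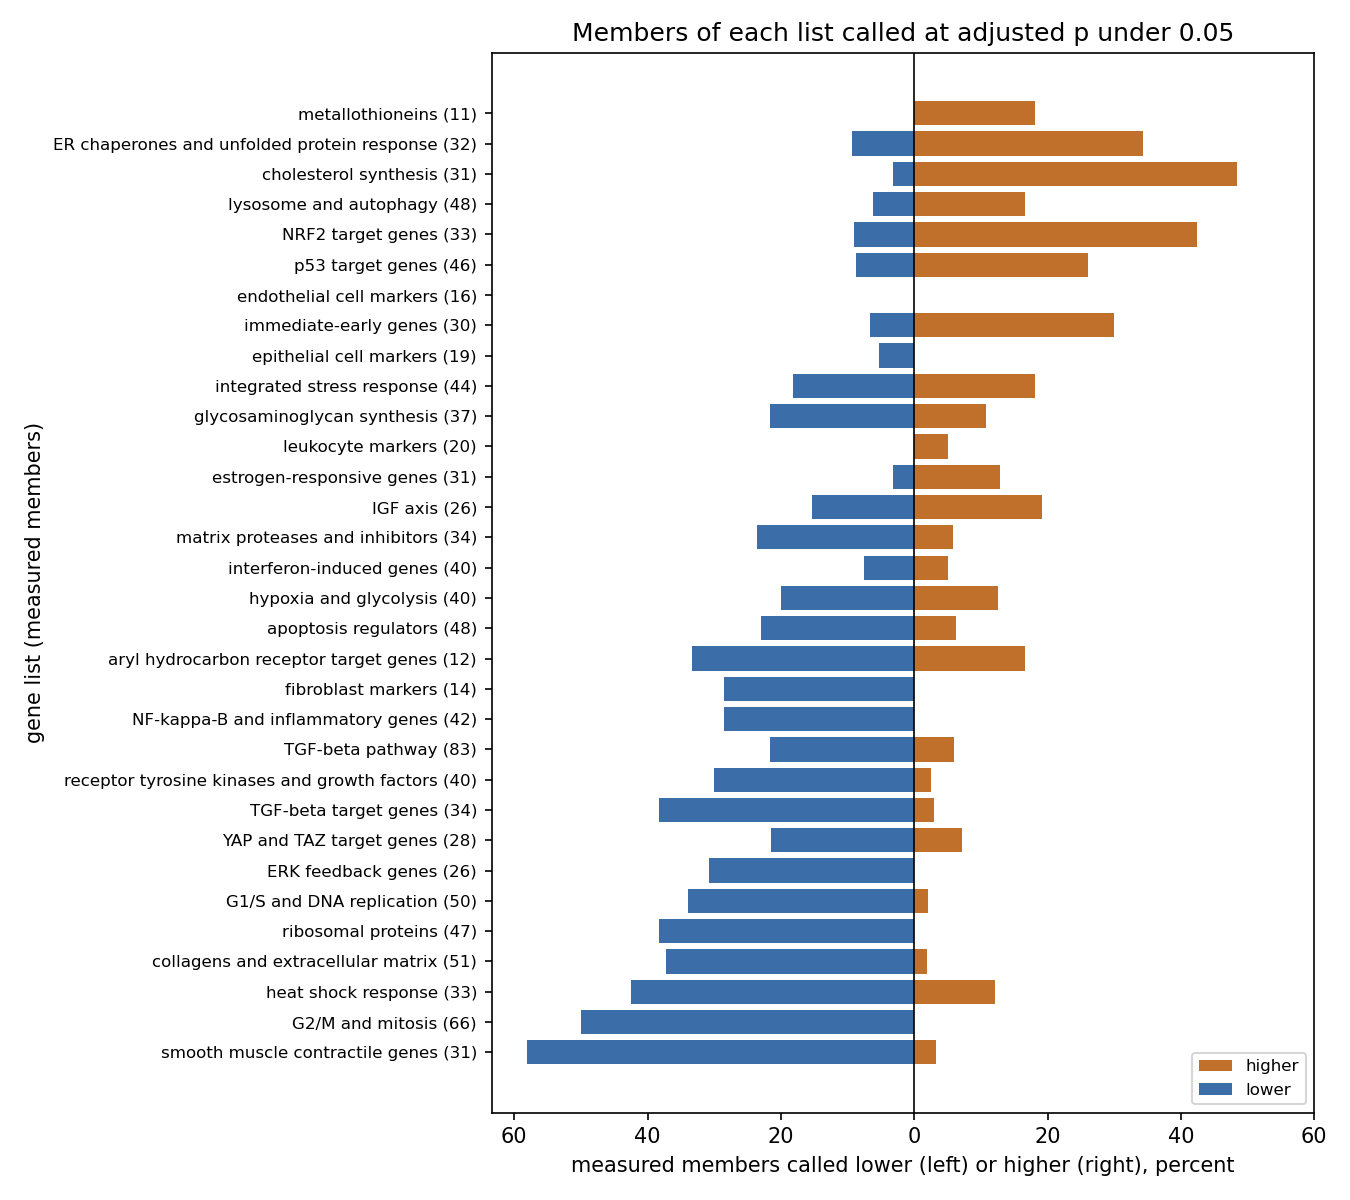
Percent of the measured members of each of the 32 gene lists called lower (left bars) or higher (right bars) at an adjusted p under 0.05, with the number of measured members in brackets and the lists ordered by median log2 ratio. Contractile genes (18 of 31 lower) and mitosis genes (33 of 66 lower) lie at one end and lists with more members higher than lower, such as cholesterol synthesis (15 of 31 higher), at the other.

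The dye-swapped arrays were set against each other to check that both arrays of a replicate point the same way. Across probes, which are not independent replicates, the turned log2 ratios of both arrays correlated at r = 0.67 in replicate 3, 0.35 in replicate 2 and -0.27 in replicate 1. On the scanner software's log ratios these were 0.49, 0.19 and -0.36. Arrays of different replicates with genistein in Cy3 correlated at 0.72 to 0.93. Those with genistein in Cy5 did so at 0.79 between replicates 2 and 3, and at 0.31 and 0.18 with the array of replicate 1. Arrays with the same dyes share a dye effect, and all share the vehicle pool, so these values would not be 0 without a treatment effect. In replicate 1, TP53INP1 stood at 2.21 with genistein in Cy3 and -0.12 with genistein in Cy5, and ACTG2 at -2.20 and -0.57. Of 2917 called genes, 1539 had the same direction on all 6 arrays and 2717 on the 5 arrays other than that of replicate 1 with genistein in Cy5. Within the slide series of 3 arrays each, of which 2 and 1 carry genistein in Cy5, the medians of 28 of the 32 lists had the same sign, and the differences between series were not tested. Only 1 series holds the array of replicate 1 with genistein in Cy5, so a series difference cannot be told apart from that array. Contractile genes had medians of -0.36 and -0.41, TGF-beta target genes -0.10 and -0.11, and G2/M genes -0.16 and -0.34. The medians of cholesterol synthesis genes were 0.11 and 0.35, of metallothioneins 0.18 and 0.39, of chaperone genes 0.10 and 0.31, of lysosome genes 0.09 and 0.27, and of fibroblast markers -0.18 and -0.05.

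**Figure D3:**
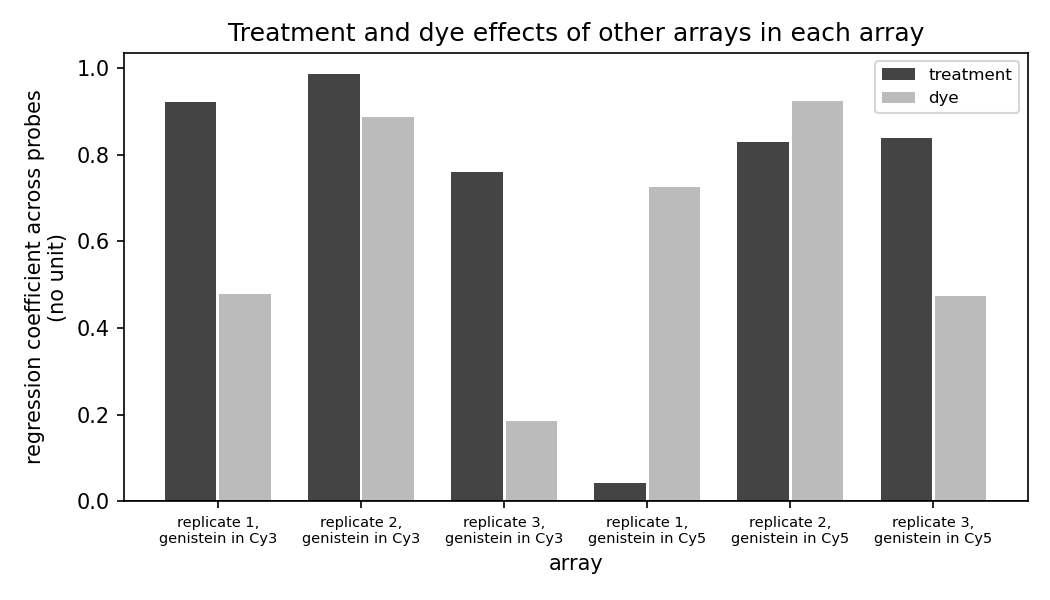
Coefficients (no unit) from regressing the log2 ratio of each of the 6 arrays across 38238 probes on the treatment effect and the dye effect, both taken from those arrays of replicates 2 and 3 that are of another replicate, signed so that 1 is the effect in the labelled direction. The array of replicate 1 with genistein in Cy5 has a treatment coefficient of 0.043, and the other arrays lie between 0.759 and 0.985.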

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

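The coefficients, the tests of explanations and the number of genes in which an array stood apart were chosen after the result was seen, and the correlations between arrays were not. The array of replicate 1 with genistein in Cy5 lay far from the other 5 in 4 of 8 summaries tested, where chance sets about 1 in 20 groups of this size apart. Its median correlation with the other arrays was -0.27, against 0.5 to 0.67, and its treatment coefficient was 0.043, against 0.759 to 0.985. The SD over the TGF-beta target genes on it was 0.303, against 0.737 to 0.781 on the others. It stood apart in 39 of 116 named genes, and the other arrays together in 1. It was also lowest, but within the limit, in the SD of all log2 ratios (0.169) and of the TGF-beta pathway (0.236) and G2/M (0.173) genes, and the share of probes above background set no array apart.

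A weak or failed hybridisation is argued against by signal, since 92% of its probes were well above background in both channels, within the range of the other arrays (85.6% to 92%), and dyes exchanged against the label by the treatment coefficient of 0.043, which would then lie below -0.5. Identical RNA in both channels is argued against, because in 39 genes whose brightest probe lay at least 0.5 from the dye effect the next probe lay on the same side in 84.6% (48.7% for random probes of like brightness). What stays open, as a hypothesis found and tested on the same data, is different RNAs of vehicle cells in both channels: the mean brightness followed the treatment effect with a coefficient of -0.555, against -0.255 to 0.126 on the other arrays, which is consistent with that and argues against RNAs of genistein cells in both. Of 258 genes changed at least 2-fold on the arrays of replicates 2 and 3, 9 kept 0.5 or more of the change on this array and 7 went as far the other way, and MMP1 (-1.11), VEGFC (-1.15) and LOXL1 (-1.01), which lay within the range of the other arrays, are left unexplained by it. No biological explanation was tested.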

How the results depend on the processing

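The tests without the array that stood apart were chosen after the result was seen. With all probes kept or the strictest filter, the counts of higher and lower genes stayed within 1.5 times those reported. The same held with an intensity trend, robust eBayes or an offset of 0. It also held for all 6 arrays taken singly with dye and slide series terms and a random block by replicate. That fit, with 888 higher and 2278 lower genes, changed several choices together. No background subtraction and the 3 arrays with genistein in Cy5 each gave 0 probes, 0 higher and 0 lower genes (limma, 5206 and 3437 genes at an unadjusted p under 0.05). Those 3 arrays include the doubted one, with a treatment coefficient of 0.043 against 0.829 and 0.838 in replicates 2 and 3. A loss on them cannot be told apart from an effect of that array. Leaving out 1 replicate gave 0 to 6741 probes, 0 to 996 higher and 0 to 2357 lower genes. Scaling between arrays gave 3138 probes, 265 higher and 1399 lower genes, and the scanner software's ratios and the series value table each gave 454 higher genes. Median centring gave 3343 lower genes. The 3 arrays with genistein in Cy3 gave 10532 probes and 1924 higher genes, with the dye effect counted as treatment. All 6 arrays taken singly, with a dye term and a random block, gave 1243 higher genes. The 1.5-fold threshold left 1214 probes, 168 higher and 543 lower genes, and the scanner software's p and fold left 27 probes on all 6 arrays and 748 on the other 5. Without the doubted array there were 9464 probes and 1543 higher genes, or 10762 and 1801 with a dye term and arrays taken singly. The cause was not tested, apart from settings built with fewer arrays or a stricter rule. In simulated data with 0.5 of the change in replicate 1, recovery of 1.5-fold changes dropped from 95.5% to 46.3%, and of 2-fold changes from 100% to 85.1%.

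Against 15 lists called, an estimated correlation called 0, median centring 9 (8 of the 15) and the arrays with genistein in Cy5, the doubted one among them, 7. Without the doubted array, an estimated correlation called 0, and camera called the TGF-beta target genes (adjusted p = 0.0305). Fry asks whether members move one way on balance, not whether they differ from other genes. It called 0 lists on all arrays and 26 without the doubted one, among them the TGF-beta pathway (0.0199) and target genes (0.00813). The target genes were also called with the mean over probes (0.0497), and ranged from 0.0372 to 0.206 with 1 replicate left out. The matrix protease and glycosaminoglycan lists pointed down in fry with all arrays (0.084 and 0.159) and without the doubted one (0.00442 and 0.0396), and up in camera in both cases. Among named genes called, log2 ratios that turned sign were those of IGFBP4 (-0.00335) with genistein in Cy5, CD79A (-0.0376) under median centring, and PIK3R1 (0.0427) and NT5E (0.0835) with genistein in Cy3. In the fits on 1 dye orientation such a turn can come from the dye effect. Of 153 named genes called, 153 lost the call with no background subtraction, 153 on the arrays with genistein in Cy5, 39 with scaling between arrays, 29 with the scanner software's ratios or the series value table, 19 under median centring, 13 on the arrays with genistein in Cy3, 8 without replicate 1, 153 without replicate 2 or 3, 5 without the doubted array and 1 with a dye term there. The other settings ended at most 11 calls. Signal over background limits dim genes such as ESR2.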

Other observations

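The array of replicate 1 with genistein in Cy5 stood apart. All tests and counts without it, also those with a dye term, were chosen after the result was seen. So were the genes named in groups of 5 or fewer, but no other test in this part was. Of 12 measured aryl hydrocarbon receptor target genes, 2 were higher, CYP1A2 (log2 ratio 0.40 ± 0.17, SD, n = 3) and NQO1 (0.32 ± 0.04), and 4 lower, ALDH1A3 (-0.87 ± 0.20), CYP1B1 (-0.65 ± 0.25), AHRR (-0.35 ± 0.04) and NFE2L2 (2 and 5 adjusted over the list alone, camera adjusted p = 0.644). Of 31 estrogen-responsive genes, 4 were higher, CA12 (0.57 ± 0.26), SGK3 (0.50 ± 0.18), IGFBP4 (0.35 ± 0.12) and NHERF1 (0.28 ± 0.08), and 1 lower, FHL2 (-0.77 ± 0.43), with the same counts adjusted over the list alone and a camera adjusted p of 0.148. The receptor genes ESR1 (-0.22 ± 0.16, adjusted p = 0.12), ESR2 (0.12 ± 0.14, adjusted p = 0.279) and PGR (-0.16 ± 0.34, adjusted p = 0.479) did not pass the test. ESR2 was well above background in the genistein channel on 2 of 6 arrays and in the vehicle channel on 3, and PGR on 4 and 5. Without the array that stood apart, 3 aryl hydrocarbon receptor targets were higher and 5 lower, and 6 and 2 estrogen-responsive genes (8 and 4 with a dye term).

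In the IGF axis, 5 of 26 measured members were higher and 4 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.186). IGF2R (0.73 ± 0.21), FOXO1 (0.68 ± 0.29), IRS1 (0.59 ± 0.27), IGFALS (0.40 ± 0.16) and IGFBP4 were the higher members, and IGFBP5 (-0.49 ± 0.17), GRB14 (-0.35 ± 0.12), PIK3CA (-0.32 ± 0.13) and PIK3R1 (-0.23 ± 0.04) the lower ones. Of 40 hypoxia and glycolysis genes, 5 were higher and 8 lower (7 and 8 adjusted over the list alone, camera adjusted p = 0.706). The glycolytic enzyme genes LDHA, HK2 and ENO1 fell by 1.20 ± 0.33, 1.07 ± 0.25 and 0.34 ± 0.04, and NDRG1 (1.00 ± 0.38), CA12, MXI1 (0.26 ± 0.11), DDIT4 (0.26 ± 0.08) and ENO2 (0.25 ± 0.04) rose. Of 37 glycosaminoglycan synthesis genes, 4 were higher and 8 lower (7 and 10 adjusted over the list alone, camera adjusted p = 0.859). The hyaluronan synthase gene HAS2 fell by 1.61 ± 0.49, EXT1 by 0.79 ± 0.23 and B3GALT6 by 0.69 ± 0.13, and DSEL (0.52 ± 0.25), CHST7 (0.35 ± 0.13), CHST15 (0.25 ± 0.07) and DSE (0.25 ± 0.08) rose. Of 48 apoptosis regulators, 3 were higher, CASP8 (0.37 ± 0.18), BAX (0.26 ± 0.01) and TRADD (0.24 ± 0.10), and 11 lower (4 and 13 adjusted over the list alone, camera adjusted p = 0.743). BID fell by 0.70 ± 0.24 and BIRC2 by 0.42 ± 0.08. Of 40 interferon-induced genes, 2 were higher, IRF7 (0.66 ± 0.29) and IFI27 (0.28 ± 0.06), and 3 lower, GBP1 (-0.94 ± 0.30), SAMD9 (-0.33 ± 0.10) and PARP9 (-0.24 ± 0.09), with the same counts adjusted over the list alone (camera adjusted p = 0.631). PIK3R1 lost its call without the array that stood apart (adjusted p = 0.239), but kept it with a dye term (0.00399). Without that array, 5 IGF axis genes were higher and 3 lower, 8 and 10 hypoxia genes, 9 and 9 glycosaminoglycan genes, 6 and 13 apoptosis regulators, and 6 and 7 interferon-induced genes. The median and the mean had opposite signs in the matrix protease (0.01 and -0.10), glycosaminoglycan (0.03 and -0.08), hypoxia (0.01 and -0.04), interferon (0.01 and -0.003) and epithelial (0.04 and -0.05) lists.

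Of 19 epithelial markers, 1 was lower, MUC1 (-0.55 ± 0.18), and 0 were higher (1 and 0 adjusted over the list alone, limma, 3 higher at an unadjusted p under 0.05, camera adjusted p = 0.2). The keratin gene KRT18, at -1.17 ± 0.69, did not pass the test (adjusted p = 0.0501), but did without the array that stood apart (-1.52, adjusted p = 5.84e-05). Of 16 endothelial markers 0 were called (0 adjusted over the list alone, limma, 1 higher and 0 lower at an unadjusted p under 0.05, camera adjusted p = 0.0827). Of 20 leukocyte markers, 1 was higher, the B cell gene CD79A (0.18 ± 0.04), and 0 were lower (0 and 0 adjusted over the list alone, limma, 3 higher and 0 lower at an unadjusted p under 0.05). The macrophage gene CD68, at 0.68 ± 0.40, did not pass (adjusted p = 0.0509). Without the array that stood apart, 2 epithelial markers were higher (1 with a dye term) and 3 lower, 3 and 0 endothelial markers, and 2 and 0 leukocyte markers, CD68 among them (adjusted p = 0.00129). The leukocyte list had a camera adjusted p of 0.0414 with a median of 0.03, and an adjusted p = 0.538 with an estimated correlation. Of 12 alternatives with camera 3 called it, with adjusted p from 0.0343 to 0.538, and it was not called without replicate 1 (0.0652), without replicate 2 (0.0551) or without the array that stood apart (0.0615).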
